A study of Solanum lycopersicum with 6 samples.

How the data were processed

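RNA sequencing libraries of tomato shoulder pericarp at 30 DPA were grouped by their titles into 3 WT and 3 slgols2 libraries. Per the file headers, the authors deposited 1 table with an FPKM value, fragments scaled by gene length and library depth, for each of 35768 gene models in each library. HISAT2 2.1.0 and DESeq 1.38.3 are named in the submitters' processing notes. The counting tool, genome build, annotation release and settings are not given in the sources used here. Nor is a strand setting, so whether reads of overlapping and antisense genes were told apart is not known.

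FPKM values are not counts, and no count model was the main test. Depth was recovered from the steps between values of low genes, which are whole multiples of what 1 fragment is worth. At the recovered depth, 99.2% of the steps of 2021 low genes gave a whole gene length within 0.01 bases. The best other depth that was not a whole fraction of it gave 3.4%. Whole fractions of a depth also give whole lengths, so the largest depth that gave them was taken. Whole read numbers within 0.02 reads in all 6 libraries followed for 15628 of the 15695 tested genes (99.6%). The reads found again in genes made up between 98.9% and 99.0% of the depth, so the depth behind the FPKM values was close to the number of reads in genes. The lowest depth was 15590000 and the highest 17940000 fragments. The recovery was tested on simulated reads, where 99.0% of 4882 simulated genes came back exactly. Floors of 3 reads cover counting error only. The median recovered gene length was 4137 bases. For 91 list members there was a recovered length and a reference gene at the matching place. The median ratio of that length to the reference gene span was 1.02, and 55 of the 91 lay within 10% of the span. Where the length was the span, values of genes with long introns are lower than with exon lengths.

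Genes with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3. The model was fitted to log2(FPKM + 1) with genotype as the only term and an intensity trend in the empirical Bayes step, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. With 3 against 3 libraries an exact permutation test of a single gene cannot go below 0.10, and none was used for calls. In a simulation on 15695 genes with the spread of each gene within the real groups, 50 genes were changed at each size. Of these, 30% were recovered at a log2 change of 1, 82% at 2, 86% at 3 and 88% at 4, with 8 false calls in all. The noise was independent between genes and equal in both groups, and changed genes had a mean log2(FPKM + 1) above 2. The rates therefore cover neither a library that stands apart nor changes in lower genes.

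The 15 gene lists were written before the data were examined, as 217 tomato gene models recalled from the literature. The deposited table holds no gene names, and the reference table (assembly SLM_r2.1) holds symbols and positions but none of the identifiers, so 0 identifiers matched. No name was therefore attached to a single gene. Values at loci recalled for single genes, the edited gene among them, were looked at before this was settled and are not reported. The lists themselves rest on recalled pairings of identifier and function, which is a limit of every list result. They were checked in bulk: of 121 recalled names found in the reference, 112 lay on the same chromosome and within 5% of the same rank among its genes, against 2.3% of shuffled names. A further 6 contradicted models were dropped, 3 carried a family name that the reference places elsewhere and were kept, 2 were absent from the table, 56 had names not in the reference and 38 had none, among them all light harvesting and seed loci. Another 16 lists defined by words in gene descriptions, vascular markers among them, were not applied because there were no descriptions.

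Lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 15 lists. Genes to be named were to be the galactinol synthase genes, the 12 with the largest rise and fall, up to 4 members per list and a set of ripening references. The rule allowed at most 2 identifiers each way where no descriptions were to be had, from genes past the threshold whose groups did not overlap and whose higher group had a mean FPKM of at least 2; these 4 are the ones given, and the parts of the rule that need names were not applied. Enrichment of chromosomes was tested with Fisher's exact test against all tested genes, using scipy 1.17.1. Chromosome numbers and gene order came from the identifiers.

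Alternatives set before the data were examined covered the pseudocount, the filter, median-ratio and quantile scaling, the intensity trend, sample quality weights, robust empirical Bayes, the replicate number as a block, each library left out, stricter thresholds, an estimated correlation in camera, and fry. Those chosen after seeing the data were limma-voom on recovered reads (18610 genes with a mean of at least 10 reads), genes outside chromosomes 4 and 5, quantile scaling for the lists, slgols2 replicate 3 alone against WT, the light harvesting list without its chromosome 2 row, and lists restricted to checked members. The median log2 change of all tested genes was 0.001, and 0.017 and 0.04 after median-ratio and quantile scaling. No pair of libraries was alike enough to be the same library deposited again. The highest correlation of log2 values between 2 libraries was 0.958.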

Results

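RNA sequencing was carried out on the shoulder pericarp, the fruit wall near the stalk, of tomato (Solanum lycopersicum cultivar Ailsa Craig) at 30 DPA. The 6 libraries formed 2 groups of 3, wild type (WT) fruit and fruit of slgols2 plants, which carried a mutation made by CRISPR-Cas9 editing. GolS is the usual abbreviation of galactinol synthase, the enzyme that makes the galactosyl donor for raffinose family sugars. The values were FPKM, fragments scaled by gene length and library depth, for 35768 gene models. The steps between low values gave depths of 17450000, 17240000 and 15590000 fragments for WT replicates 1, 2 and 3, and of 17940000, 16050000 and 16330000 for slgols2 replicates 1, 2 and 3. Between 14878 and 15647 gene models reached 1 FPKM in a library. Nothing in the labels says whether the replicates came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

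The design gave a single comparison, slgols2 against WT fruit at the same stage, which asks which transcripts differed in level in the mutant fruit wall. Gene identifiers were not paired with gene names in the sources used here, so no row is reported as the edited gene and no check of the knock-out labels on its values is given. Genes are therefore described by lists of loci fixed before the data were examined, with 4 gene models given by identifier.

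Of the 15695 gene models tested, 36 differed between slgols2 and WT fruit at an adjusted p of 0.05 (limma, Benjamini-Hochberg). They comprised 11 with higher and 25 with lower levels in slgols2. Many were present in one genotype and listed at 0 in the other. Of the 25 lower genes, 10 were at 0 in all 3 slgols2 libraries, and 5 of the 11 higher genes were at 0 in all 3 WT libraries. Some of these rested on few recovered reads. A higher gene on chromosome 5 had 3, 3 and 2 reads in the slgols2 libraries, and a lower gene on chromosome 4 had 4, 7 and 4 in WT. By the chromosome number in the identifiers, 11 of the 36 lay on chromosome 4, where all 11 were lower in slgols2, against 2.94 expected from the genes tested there (one-sided Fisher's exact test, adjusted p = 0.0012 over 13 chromosome groups). Chromosome 5 held 7, of which 6 were higher in slgols2, against 2.48 expected, which did not pass the adjustment (adjusted p = 0.0678).

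**Figure D1:**
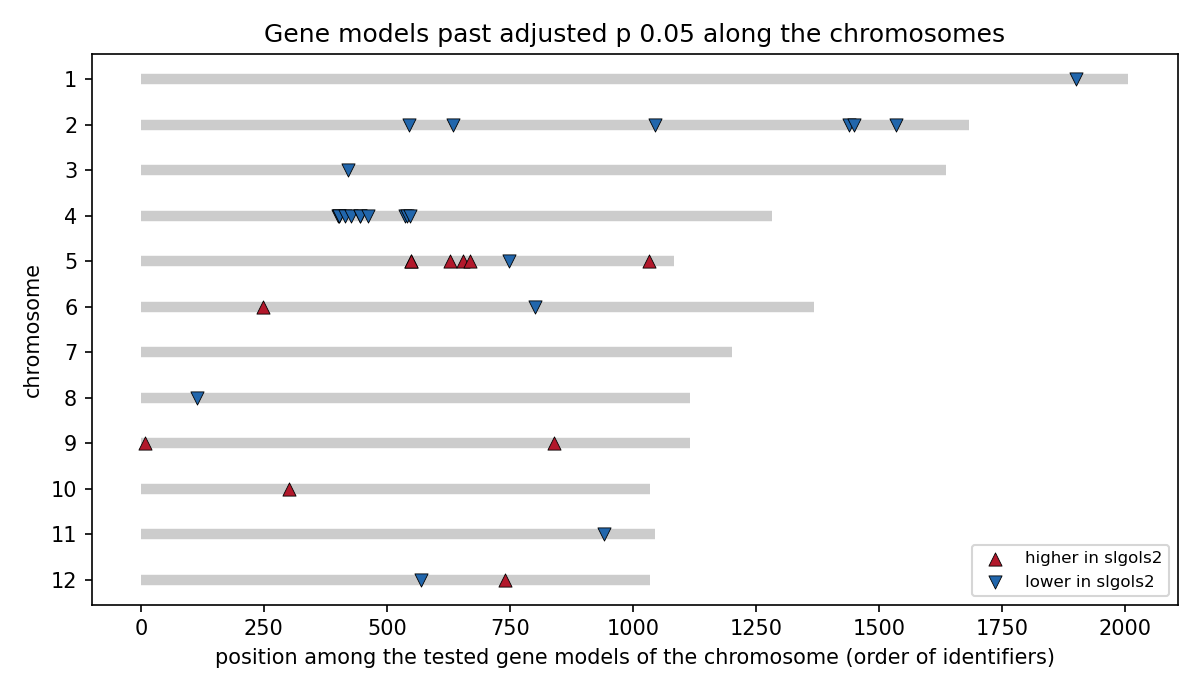
Gene models past an adjusted p of 0.05 along the 12 chromosomes; the x axis is the position among the tested gene models of the chromosome in the order of their identifiers, the y axis is the chromosome, and each grey bar spans the models tested. Triangles that point up are higher and triangles that point down lower in slgols2; chromosome 4 holds 11 models, all lower, and chromosome 5 holds 7, of which 6 are higher, while 1 model with no assigned chromosome is not drawn.

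Solyc04g018080.3, on chromosome 4, stood at 29.8 ± 2.63 FPKM in WT (SD, n = 3) and was listed at 0 in all 3 slgols2 libraries. Set against a floor of 3 reads per library, it was at least 195-fold lower in slgols2, and on the log2(FPKM + 1) scale it fell by 4.94 with a standard error of 0.13 (limma adjusted p = 0.00018). Solyc02g070990.1, a member of the light harvesting list, stood at 117 ± 100.5 FPKM in WT and 0.649 ± 0.873 FPKM in slgols2 (SD, n = 3 each), and fell by 5.96 with a standard error of 0.64 (limma adjusted p = 0.0352). The FPKM sum of this and the neighbouring list members was 1156 ± 491 in WT and 329 ± 34.4 in slgols2 (SD, n = 3), which did not overlap (two-sided exact permutation p = 0.10, the smallest that 3 against 3 allow). Its neighbours by identifier are members of the same list, and near-identical copies can share reads, so its own level is uncertain. Solyc05g041700.1, on chromosome 5, was listed at 0 in all 3 WT libraries and stood at 37.3 ± 14.7 FPKM in slgols2 (SD, n = 3), at least 54.6-fold higher than the floor (log2 change 5.19, standard error 0.27, limma adjusted p = 0.00243). Solyc05g032670.2 was likewise listed at 0 in WT and stood at 9.30 ± 3.21 FPKM in slgols2 (SD, n = 3), at least 199.7-fold higher than the floor (log2 change 3.31, standard error 0.26, limma adjusted p = 0.00993).

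The 36 genes were all separated, with the 3 values of one group above the 3 of the other. For called genes this follows largely from the small p that a call needs, so it adds no support. Among all tested genes 19.2% were separated in this way, against 10% by chance. An unadjusted p under 0.05 was found for 1877 genes, against 785 expected by chance. The number past the adjusted threshold moved when single libraries were left out: it was 7 without WT replicate 1, 9 without WT replicate 2, 34 without WT replicate 3 (21 of them among the 36), 14 without slgols2 replicate 1, 23 without slgols2 replicate 2 and 279 without slgols2 replicate 3. Of the 4 gene models given, Solyc02g070990.1 lost its call without WT replicate 1 or 2 or slgols2 replicate 1 or 2 (limma adjusted p up to 0.148), and Solyc05g032670.2 without WT replicate 1 or 2 or slgols2 replicate 1 (up to 0.0823). With limma-voom on read numbers recovered from the FPKM steps, chosen after seeing the data, the number was 2, and Solyc02g070990.1, Solyc05g041700.1 and Solyc05g032670.2 lost their calls (adjusted p = 0.222, 0.0559 and 0.0559). The number was 2028 (953 higher and 1075 lower) with limma's sample quality weights, 20 with a pseudocount of 0.1, 55 with no filter and 15 at a mean FPKM of at least 5, and Solyc02g070990.1 also lost its call with that pseudocount (limma adjusted p = 0.0807) and with no filter (0.0522).

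The libraries of slgols2 were less alike than those of WT. Correlations of log2(FPKM + 1) across tested genes, which are not independent replicates, ran from 0.924 to 0.958 within WT. Within slgols2, replicates 1 and 2 correlated at 0.957, and replicate 3 correlated with them at 0.849 and 0.869. Replicate 3 of slgols2 correlated more highly with each WT library, at 0.891, 0.903 and 0.878 for WT replicates 1, 2 and 3, and lay on the WT side of the first principal component (42.7% of the variance), at -32.7 against -38.4, -24.7 and -11.4 for WT and 62.6 and 44.6 for slgols2 replicates 1 and 2. Between groups all correlations lay between 0.858 and 0.914.

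Of the 15 gene lists, 4 differed between slgols2 and WT in camera's test with its preset correlation of 0.01, namely light harvesting, heat shock, epidermis and cuticle, and flavonoid. With an estimated correlation none passed (camera adjusted p = 0.719 for each of the 4). The estimates were 0.61, 0.45, 0.75 and 0.30 in that order, so the preset p-values below rest on a correlation much lower than estimated. At the preset, another split of the 6 libraries into 3 and 3 gave 7 lists past the threshold. Over all lists, 171 members were tested and 1 passed the threshold over all genes. In the directional test of limma's fry no list passed (adjusted p = 0.421 for each of the 4). Fry's mixed test lets members change either way, so it shows no direction. There, light harvesting and epidermis and cuticle passed (adjusted p = 0.0433 for each), but heat shock (0.191) and flavonoid (0.310) did not. Chlorophyll synthesis, with 6 members higher and 8 lower, had the lowest value (0.0159), and no other list passed.

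The light harvesting list, which holds loci for the chlorophyll-binding antenna proteins, was lower in slgols2 (camera adjusted p = 1.78e-06). Of its 23 tested members 22 had a lower mean of log2(FPKM + 1) in slgols2, with a median log2 change of -0.78. A single member passed the threshold over all genes and 3 passed when adjusted over the list alone, all lower in slgols2. The list median was lowest in slgols2 replicate 3, the library that stood apart, at -1.50 relative to the WT mean on the log2 scale. In that library 22 of the 23 members lay below the lowest WT value, though not every member was lowest there. The medians were -0.30 and -0.10 in slgols2 replicates 1 and 2, against -0.32, -0.05 and 0.43 in WT replicates 1, 2 and 3. Without slgols2 replicate 3 the list no longer passed (camera adjusted p = 0.112). None of this list's loci carried a name that could be set against the reference.

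The heat shock list, of heat shock factors and chaperones, was higher in slgols2 (camera adjusted p = 0.000584). Of its 15 tested members 13 had higher mean values, with a median log2 change of 2.66, and none passed the threshold either over all genes or adjusted over the list alone. The difference came from 2 of the 3 slgols2 libraries: list medians relative to the WT mean were 4.76 in replicate 1 and 3.24 in replicate 2, but -0.02 in replicate 3, against 0.14, 0.03 and -0.18 in WT. In slgols2 replicates 1 and 2, 12 of the 15 members exceeded the highest WT value, and 6 did so in replicate 3. When the list was restricted after seeing the data to the 6 tested members whose recalled name lay at the matching place in the reference, it did not pass (camera adjusted p = 0.795). Among these 6, those recalled as heat shock factors had log2 changes of 0.05, -0.48 and -0.87, and those recalled as chaperones 4.62, 3.08 and 3.31. The restricted test thus mixed members that rose with members that did not.

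The epidermis and cuticle list, markers of the outer cell layer of the fruit, was lower in slgols2 (camera adjusted p = 0.00118). All 5 tested members had lower mean values, with a median log2 change of -0.62; none passed over all genes and 1, lower in slgols2, passed when adjusted over the list alone. The list medians were -1.64, -0.68 and -0.29 in slgols2 replicates 1, 2 and 3, below the WT medians of -0.13, 0.20 and 0.06. The flavonoid list, of genes for flavonoid synthesis and its regulator, was also lower (camera adjusted p = 0.0141), with all 6 tested members lower in mean, a median log2 change of -0.64 and no member past the threshold over all genes or adjusted over the list alone. It did not pass without slgols2 replicate 2 (camera adjusted p = 0.0811). The seed list, markers of another tissue of the fruit, did not pass in the full comparison (camera adjusted p = 0.780), with medians of -1.48, 1.43 and -1.33 in slgols2 replicates 1, 2 and 3 and of -0.77, -0.43 and 1.23 in WT.

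**Figure D2:**
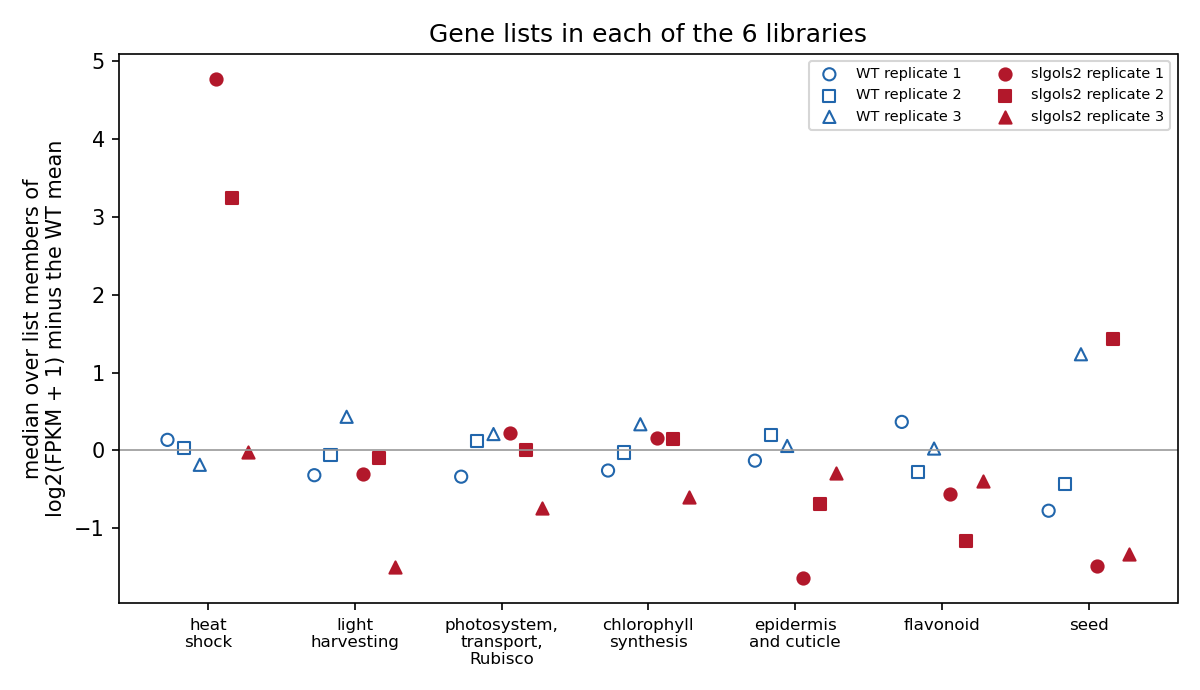
Median over the tested members of 7 gene lists of log2(FPKM + 1) minus the WT mean (y axis), for each list (x axis) and library; open blue symbols are the 3 WT libraries, filled red symbols the 3 slgols2 libraries, and the grey line marks the WT mean. The heat shock medians of slgols2 replicates 1 and 2 are 4.76 and 3.24 while replicate 3 is at -0.02, and the light harvesting median is lowest in slgols2 replicate 3, at -1.50.

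The ripening and pigment lists did not pass camera's test. Members counted as higher or lower here are so in the mean of log2(FPKM + 1). The ripening regulators had 2 of 7 tested members higher and 5 lower (adjusted p = 0.590). Their medians relative to the WT mean were -0.26 and -0.29 in slgols2 replicates 1 and 2 but 0.33 in replicate 3. In WT they were 0.01, 0.02 and -0.08. The ethylene synthesis and response list had 8 of 14 higher (adjusted p = 0.780). The carotenoid pathway had 9 of 22 higher (adjusted p = 0.542), and the fruit softening cell wall list had 3 of 5 higher (adjusted p = 0.851). Among the chloroplast lists, the chloroplast development regulators had 8 of 11 members higher (adjusted p = 0.542), chlorophyll synthesis had 6 of 14 higher (adjusted p = 0.714), and photosystem, electron transport and Rubisco had 3 of 14 higher (adjusted p = 0.590). The sucrose and starch list had 5 of 15 members higher in mean (adjusted p = 0.590). The abscisic acid and dehydration list had 4 of 6 higher (adjusted p = 0.938), and the steroidal glycoalkaloid list had 4 of 9 higher (adjusted p = 0.590). In these lists no member passed over all genes, and 1 member of the chlorophyll synthesis list, higher in slgols2, passed when adjusted over the list alone. The median, the mean and the direction of the test differed in sign for 5 of the 15 lists, none of them among the 4 that passed.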

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

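The count of 36 genes stayed within 1.5 times under median-ratio scaling (37), quantile normalization (34), no intensity trend (34), robust empirical Bayes (33) and a fold of at least 2 (36). It was 20 with a pseudocount of 0.1, 55 with no filter, 15 at a mean FPKM of at least 5, 16 at an adjusted p of 0.01 and 2028 with sample quality weights. Leaving out each library gave 7 to 279 genes, the extremes being without WT replicate 1 and without slgols2 replicate 3. No gene of the 36 could change direction in these 6 fits, since the groups of all 36 did not overlap. Of the alternatives chosen after seeing the data, limma-voom on recovered reads gave 2 and the genes outside chromosomes 4 and 5 gave 9. A stricter threshold or filter tests or passes fewer genes by construction; otherwise the cause was not tested.

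With the replicate number as a block, 1 gene passed, Solyc04g018080.3, while Solyc02g070990.1, Solyc05g041700.1 and Solyc05g032670.2 had adjusted p of 0.193, 0.097 and 0.138. The numbers are not shown to pair the libraries: deviations from the group means of libraries with the same number correlated at -0.15, 0.089 and -0.165, and only the libraries numbered 2 correlated best with each other. The block changed no call of a list.

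The 4 lists kept the direction given by camera or fry under every alternative run on them. In slgols2 replicate 3, however, the heat shock median was -0.02 relative to the WT mean on the log2 scale, so that direction shows no rise there. None passed with an estimated correlation (adjusted p = 0.719 each) or directional fry (0.421 each). Over the fits that leave out 1 library, adjusted p ranged from 9.62e-10 to 0.112 for light harvesting, from 0.00389 to 0.0811 for flavonoid, and from 0.0101 to 0.947 for seed, which passed only without slgols2 replicate 2. Chosen after seeing the data, slgols2 replicate 3 alone against WT gave 1.26e-11 for light harvesting, 0.94 for heat shock, 0.28 for epidermis and cuticle and for flavonoid, 0.0106 for chlorophyll synthesis and 0.0109 for photosystem, electron transport and Rubisco; its lone slgols2 library was assumed to vary as the WT libraries did. With an estimated correlation that single library gave 0.954 for heat shock and 0.872 for light harvesting, epidermis and cuticle, flavonoid, chlorophyll synthesis and photosystem, electron transport and Rubisco. Light harvesting without its chromosome 2 row gave 0.00716, and 0.841 with an estimated correlation. Heat shock restricted to checked members gave 0.795. The cause was not tested. The 4 gene models given by identifier were chosen for groups that did not overlap, so the direction they kept wherever they were fitted says little. Of them, Solyc04g018080.3 passed in 16 of 16 alternatives, Solyc05g041700.1 in 14 of 16, Solyc05g032670.2 in 10 of 15 and Solyc02g070990.1 in 8 of 16, with adjusted p up to 0.0488, 0.097, 0.138 and 0.222. At this depth short genes of a few FPKM rest on few reads.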

Other observations

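Apart from the test of neighbouring genes on chromosomes 4 and 5, the tests here were chosen after the results they bear on had been seen. Over all 35768 gene models, 16 reached 1 FPKM in all 3 WT libraries and were listed at 0 in all 3 slgols2 libraries, and 6 showed the opposite. Of the 16, 13 lay on chromosome 4, and of the 6, 3 lay on chromosome 5. The other 9 splits of the 6 libraries into 3 and 3 gave at most 1 such gene. A single gene model, the highest in WT replicate 1, took 13.1% of the FPKM sum there, at 55446 FPKM, and 5.96% in WT replicate 2, at 23352 FPKM, but stood at 1095 FPKM in WT replicate 3 and between 4484 and 10366 FPKM in the slgols2 libraries. Its difference between the groups did not pass the threshold (log2 change -0.87, limma adjusted p = 0.845).

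The pattern to be explained is the excess of changed genes on chromosome 4, 11 of 36 against 2.94 expected. A loss of the edited gene acting on genes wherever they lie was tested on genes outside it, those at an unadjusted p under 0.05 that did not pass the adjusted threshold. On chromosome 4 they made up 13.5% of the tested genes that did not pass, against 11.6% elsewhere (one-sided Fisher's exact test, adjusted p = 0.0246). This met the criterion first written against this explanation. Chromosome 5 had 13.8% against 11.6% (same test, adjusted p = 0.0246). Chromosome 12, looked at after the p of chromosome 4 was seen, had 14.3%. The criterion was then changed to ask for more than the spread between chromosomes. These genes therefore leave the explanation open. It also asks that genes past the threshold be spread as the tested genes are. On chromosome 4 they were not (one-sided Fisher's exact test, adjusted p = 0.0012). This argues against it for those genes, though that excess is the pattern itself. A stretch of genome that differs between the lines may account for genes at 0 in one genotype; genes of each stretch that did not pass had a median absolute limma statistic at the 65.8th percentile of equally long windows elsewhere for chromosome 4 and the 93.3rd for chromosome 5. Neither reached the 95th percentile set beforehand nor fell low enough to count against it. The measure leaves out the genes that passed, so it cannot weigh a stretch that differs by a few absent or extra genes. This explanation stays open. The 11 genes that passed on chromosome 4 lay within 147 of its 1283 tested models, and the 7 on chromosome 5 within 486 of 1083.

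The rise of the heat shock list in slgols2 replicates 1 and 2 is hard to set down to an effect of genotype alike in every slgols2 library, since the list median of replicate 3 was -0.02, with member quartiles of -0.54 and 0.48, against lower quartiles of 1.99 and 1.13 in replicates 1 and 2. A WT sample under the label of slgols2 replicate 3 would go with its higher correlation with each WT library (0.878 to 0.903) than with the other slgols2 libraries (0.849 and 0.869), but is argued against by the genes at 0 in one group and on in the other over the other 5 libraries: 22 of 35 (62.9%) followed the slgols2 side in replicate 3 and 4 the WT side, while WT libraries left out in the same way had at most 14.3% of such genes on the slgols2 side. This comparison replaced a first criterion, over 80% or under 20%, that left the question undecided at 62.9%. Of the 22 genes, 13 lie on chromosome 4 and may not be independent of each other. The comparison also does not show whether replicate 3 carries the edit. A difference in the handling or harvest of single fruits, or an effect of genotype that shows only under some conditions, may remain, and the labels record neither date nor batch. The epidermis and cuticle list, markers of the outer cell layer, also changed most in slgols2 replicates 1 and 2. Its medians were -1.64 and -0.68 there and -0.29 in replicate 3, all below the WT medians. Whether the 2 lists go together was not tested.

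The lower light harvesting list had 2 parts. In the chromosome 2 row, all 6 tested members lay below the lowest WT value in each slgols2 library, and reads moving between those copies are argued against by their FPKM sum, whose highest slgols2 value was 41.4% of the lowest WT value; copies elsewhere were not tested. Outside the row, 16 of 17 members lay below the lowest WT value in slgols2 replicate 3, but 6 and 5 in replicates 1 and 2, near the 4.25 expected by chance, and the list without the row passed at the preset correlation (camera adjusted p = 0.00716) and not with an estimated correlation (adjusted p = 0.841). For the whole list, row included, an effect of genotype alike in every slgols2 library cannot be told apart from an effect of 1 library, since it did not pass without slgols2 replicate 3 (adjusted p = 0.112). Less green tissue in that library may be a candidate explanation, but the photosystem, electron transport and Rubisco list was lower in it alone at the preset correlation (adjusted p = 0.0109) and not with an estimated correlation (adjusted p = 0.872), so it stays open.

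The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 36 genes and the highest other split 0, so that 1 of the 10 splits gave as many. For the lists, the real split gave 4 past the threshold and the highest other split 7, and 6 of the 10 splits, the real one included, gave at least 4. The number of lists past the threshold thus did not set the split by genotype apart from other splits.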
